A study of Mus musculus with 40 samples.

How the data were processed

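The measurements are TempO-Seq counts from 40 libraries of mouse duodenum, made per the labels' protocols from fixed, paraffin-embedded sections that were scraped off their slides and lysed. The deposited table holds whole-number counts per probe, with no normalization by the authors that the values or its header show. The submitters' processing notes name bcl2fastq 2.17.1.14, Bowtie with no version and the mouse genome build mm9, without the step each served; probe positions are not given in the sources used here, and no coordinates are printed. Symbols are those of the table, set in mouse case with a RefSeq gene table, in which 155 symbols had no match. Each column was matched to its sample by the title in the labels, and the group was taken from the labelled exposure. Replicate numbers follow accession order and only name libraries. No pair of libraries in a group was identical.

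The table holds 3045 probes for 2756 symbols, 289 of which have 2 probes, and each probe was tested by itself. Where a named gene has 2 probes, the one with more counts is given. The other probe passed as well for Nr1i3 and Vegfa in the comparisons that name them, and did not pass for Acat2, Aldh3a2, Ccna2 and Tsc22d3. Of 121800 values, 28.5% were 0, while among values above 0 only 1.01% lay from 1 to 5 and 2.93% from 21 to 25, so a count of 0 in a single library says little about a low transcript. Total counts, from 1763440 to 7904819 per library with a median of 4682822, limit the precision of low genes. The assay amplifies ligated probes by PCR and no molecular identifiers are given in the sources used here, so floors cover counting error only; whether low counts were removed before deposit is not given in the sources used here, and if they were, a fold against a group at 0 is no lower bound. A probe may detect near-identical family members, such as those of the glutathione transferase, Cyp2a, heat shock and trypsin families, and calls for those genes are uncertain as single genes.

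Counts were analysed in R 4.3.3 with edgeR 4.0.16. Probes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 2541. Libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 40 libraries, with 34 residual degrees of freedom. A probe is said to have passed, or to have been called, at a Benjamini-Hochberg adjusted p under 0.05 over the tested probes of a comparison. Tests are 2-sided. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic, an approximation. Means and SDs in CPM use TMM-scaled library sizes, and log2 CPM values a prior count of 2. The 11 comparisons were each exposed group against control, the dose steps of captan and folpet, captan against folpet at the lower and at the higher doses, and Cr(VI) against the higher dose of each; an interaction term compared the dose steps. On simulated counts with 200 changed probes, edgeR recovered 33.8% of 2-fold and 57.6% of 4-fold changes for Cr(VI) against control, with 4.39% false calls, and 30.8% and 56.4% for folpet 16000 ppm against control, with 4.39% false calls. For the interaction edgeR gave 9.09% false calls. In 1 simulation for each comparison that was simulated, DESeq2 gave between 8.00% and 20% false calls, and limma-voom between 1.45% and 7.46%. DESeq2 gave 15.7% for Cr(VI) against control and 20% for captan against folpet at 6000 ppm. The counts were drawn with edgeR's own scaling and dispersions, which may favour edgeR, and edgeR had 5 simulations per comparison. These rates therefore do not rank the tools, and the larger counts of DESeq2 are not taken as firmer. The simulated probes varied independently, so shifts that many probes of 1 library share are missing from these counts. The shares of false calls and of recovered changes in the real data may differ from the simulated ones.

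The comparisons, 34 gene lists for pathways and cell types, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 30 had at least 5 tested genes and were tested with camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. Of 82 camera calls with the preset correlation, 8 held with an estimated correlation. A gene count adjusted over the list alone applies the Benjamini-Hochberg method to the list's own p-values. The NRF2 and glutathione list is called the NRF2 list, and its members NRF2 genes, for short. It also holds the regulators Nfe2l2 and Keap1 and antioxidant genes such as Cat and Sod1. The activity of NRF2 itself was not tested. List scores are means of log2 CPM, compared by exact permutation, with bootstrap intervals from 10000 resamples (seed 20).

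Named genes are, for each comparison with control, the 6 largest rises and 6 largest falls among called probes whose exposed libraries all lie on 1 side of the control mean, and up to 3 called members in the main direction and 1 in the other of each list that camera called or that holds at least 3 called genes. For comparisons between exposures they are the 5 largest called changes each way. Lgr5, Olfm4, Tfrc, Muc2, Chga and Alpi of a fixed set of 25 genes had no probe. This set and the most significant common calls complete the rule. From the genes it gave, those printed were chosen with a preference for calls that hold in every fit leaving out 1 library, after these fits had been seen. The printed genes are thus firmer than the calls as a whole. Of the calls against control, 72 of 151 for Cr(VI), 66 of 131 and 76 of 157 for captan, and 89 of 158 and 167 of 320 for folpet held in every such fit.

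Alternatives were DESeq2 1.42.0, limma 3.58.1 voom with quality weights, other scalings (DESeq2 size factors, upper quartile, library totals alone), no filter, no robust dispersion, only the compared groups in the fit, a threshold of 0.1, libraries thinned to the smallest total, probes of a gene summed, and each library left out in turn. DESeq2 gave no adjusted p for some probes, and these were left out of counts of lost calls. They numbered 838 for Cr(VI) against control, 1330 for the folpet dose step, 1823 for captan against folpet at 6000 ppm and 1872 at the higher doses. DESeq2 adjusted over the remaining probes, so its counts and those of edgeR rest on different numbers of probes. The share of counts in acinar genes as a covariate, the removal of these genes, the removal of libraries over 50% acinar, lists and common calls without control replicate 5, and lists with each other library left out in turn were added after the data were seen. Removing the libraries over 50% acinar takes out control replicates 4 and 5, so calls against control may be lost there for fewer controls alone. No library was far shallower than the others by the rule set for depth, so none was left out for depth.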

Results

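The series measured RNA from the duodenum, the first part of the small intestine, of male B6C3F1 mice, a hybrid laboratory strain, after 28 days of exposure. The RNA came from sections of formalin-fixed, paraffin-embedded tissue and was read with TempO-Seq, a targeted assay in which pairs of short DNA probes that lie side by side on a transcript are ligated, amplified and sequenced. The 40 libraries fall into 6 groups. The control group held 5 libraries and each exposed group held 7. The first exposed group received hexavalent chromium, Cr(VI), at 180 ppm in drinking water. The others received captan at 6000 or 12000 ppm, or folpet at 6000 or 16000 ppm, in the diet. Captan and folpet are fungicides that share a trichloromethylthio group on an imide nitrogen. Captan carries it on a partly saturated ring system and folpet on an aromatic one. The labels do not say whether each library came from a different mouse, so p-values measure the spread between these libraries, which may in part be technical.

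The count table held 3045 probes for 2756 gene symbols. Total counts ran from 1763440 to 7904819 per library, and the group medians from 3536592 to 5546708. The shallowest library of the control group, replicate 5, had 2121824 counts and 1460 probes above 0, against up to 2322 probes in the other controls.

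Transcripts of pancreatic acinar cells, which make digestive enzymes, took a large and uneven share of the counts. They made up 44.9 ± 21.6% of the counts in control (mean ± SD, n = 5) and 49.7 ± 24.3% after Cr(VI) (n = 7). The share was 15.8 ± 14.3% and 9.70 ± 18.4% in the lower and higher captan groups and 17.4 ± 13.2% and 23.9 ± 10.2% in the lower and higher folpet groups (n = 7 each). Against control, 2-sided exact permutation tests gave p = 0.737 for Cr(VI), 0.0202 and 0.0189 for captan, and 0.0177 and 0.0442 for folpet. Adjusted over the 11 comparisons by the Benjamini-Hochberg method, the exact p-values of the captan and folpet groups lay between 0.0556 and 0.0810, so none passed. Control replicates 4 and 5, Cr(VI) replicates 2, 3 and 7 and captan 12000 ppm replicate 7 each held over 50% acinar counts. Because the share was lower in every captan and folpet group than in control, it is given below beside the gene groups it moved with.

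**Figure D1:**
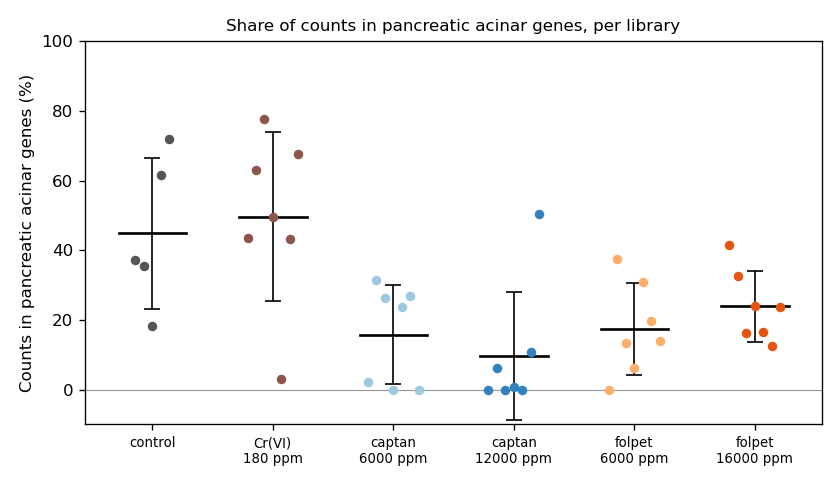
Percent of each library's counts in pancreatic acinar transcripts (y axis) by group (x axis). Points are libraries, horizontal lines group means and error bars ± SD; control and Cr(VI) means were 44.9% and 49.7%, and the captan and folpet means lay between 9.70% and 23.9%.

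The Cr(VI) group was set against control to find the response of the duodenum to 180 ppm in drinking water (n = 7 against 5). Some genes of fatty acid use and hypoxia were higher after Cr(VI), and the antigen presentation gene Cd74 and some genes of the smooth muscle and proliferation lists were lower. Creb3l3, a transcription factor of lipid metabolism in gut and liver, rose from 1874 ± 549 to 4259.8 ± 426 CPM (counts scaled by library size, mean ± SD). Cd74, the invariant chain of MHC class II, fell from 15984 ± 6617 to 4149 ± 1079.9 CPM. Their log2 fold changes were 1.18 ± 0.17 and -1.95 ± 0.29 (± standard error here and below), with adjusted p = 1.17e-05 and 5.68e-05 in the edgeR quasi-likelihood test, Benjamini-Hochberg. All 7 exposed libraries lay on the same side of the control mean for each of them. The rule for the largest rises and falls requires this, so here and below it adds no support for genes chosen by that rule.

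In the fatty acid list, 9 of 27 measured genes rose and 18 did not pass the test, and 9 rose when adjusted over the list alone. Besides Creb3l3, they included Eci1, an enoyl-CoA isomerase of beta-oxidation, at 0.93 ± 0.21 log2, and the nuclear receptor Ppara at 0.86 ± 0.20. In the hypoxia and glycolysis list, 4 of 31 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Bnip3, a mitophagy receptor induced in hypoxia, rose by 2.10 ± 0.42 log2, the glycolytic enzyme Pfkl by 1.49 ± 0.34 and carbonic anhydrase Car9 by 1.13 ± 0.24. Of the 12 enterocyte genes, 3 rose (4 adjusted over the list alone), among them the villus transcription factor Klf4 at 1.32 ± 0.24 and the apolipoprotein Apoa1 at 1.13 ± 0.23. The largest adjusted p of these 8 genes was 0.00406 (edgeR quasi-likelihood test, Benjamini-Hochberg). Camera with a preset correlation called the fatty acid, hypoxia and enterocyte lists higher, and with an estimated correlation their adjusted p was 0.194, 0.0585 and 0.341. Lists were also tested with each library left out in turn, which was chosen after the data were seen. Control replicate 5 had the lowest mean log2 CPM of the control group in all 3 lists. When it was left out, the differences between Cr(VI) and control in these means went from 0.58, 0.76 and 0.56 to 0.30, 0.42 and 0.15 log2 in the same order, the median fold changes from 0.36, 0.38 and 0.31 to 0.27, 0.48 and 0.16, and camera did not call the enterocyte list (adjusted p = 0.152).

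Of the 78 proliferation genes, 7 fell, both over all probes and when adjusted over the list alone. They included the replication licensing factor Mcm7 at -1.24 ± 0.27 log2 and cyclin Ccna2 at -0.84 ± 0.21, while Mki67 did not pass at -0.57 ± 0.56. Of 8 smooth muscle genes, 2 fell (5 adjusted over the list alone), with the actin crosslinker Flna at -1.63 ± 0.30. Of 20 heat shock genes, 2 fell, and 1 rose and 6 fell when adjusted over the list alone; the Hsp90 co-chaperone Fkbp4 was at -0.59 ± 0.13. Camera called these 3 lists lower with the preset correlation, with adjusted p = 0.217, 0.217 and 0.144 with an estimated correlation. In the NRF2 and glutathione list 3 of 43 rose (3 adjusted over the list alone), among them Maff at 1.17 ± 0.27, a small partner of NRF2. Camera called this list higher, with adjusted p = 0.614 with an estimated correlation. It did not call the NRF2 list without Cr(VI) replicate 6 (adjusted p = 0.0503) or the heat shock list without control replicate 5 (adjusted p = 0.0519), and without the latter 3 proliferation and 1 NRF2 genes passed. In the xenobiotic list 5 of 33 rose and 1 fell (5 and 2 adjusted over the list alone), with the P450 reductase Por at 1.22 ± 0.19; camera did not call the list (adjusted p = 0.0757), and its median was 0.22 where its mean was -0.21. The p53 target Cdkn1a did not pass at 0.18 ± 0.18 log2.

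In all, 151 of 2541 probes passed the test after Cr(VI), 75 higher and 76 lower, and 251 passed at a threshold of 0.1. The larger rises included Capg, an actin-capping protein, at 2.91 ± 0.57 log2, the vesicle GTPase Rab31 at 2.30 ± 0.52, the steroid dehydrogenase Hsd3b2 at 2.01 ± 0.40 and the circadian transcription factor Dbp at 1.90 ± 0.31. Control replicate 5 had a count of 0 for Rab31, Hsd3b2 and Bnip3, and control replicate 2 for Capg. Gzma, a protease of cytotoxic lymphocytes, fell by 2.62 ± 0.51 log2. The count was 240 with DESeq2, 71 with limma-voom, 28 with only the compared groups in the fit and 51 without the libraries over 50% acinar; with library totals alone, which moved the median of all probes by -0.27 log2, it was 3 higher and 11 lower. Of the 20 passing genes named here, 6 kept their call with library totals alone, 11 with limma-voom and 7 with only the compared groups in the fit. Without the libraries over 50% acinar, 45 of the 151 were kept and Apoa1, Ccna2, Fkbp4, Maff, Mcm7 and Rab31 were not, Ccna2 was also lost without control replicate 5 (-0.63 log2), and Mcm7 moved to -0.79.

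Captan at 6000 ppm was set against control to find the response to the lower captan dose (n = 7 against 5). Some genes of glutathione conjugation and of drug metabolism were higher, and a few genes of smooth muscle and connective tissue were lower. Gsta2, a glutathione transferase, rose from 240.1 ± 105 to 2488 ± 1283 CPM (mean ± SD), a log2 fold change of 3.37 ± 0.51. The carbonyl reductase Cbr3 rose by 3.25 ± 0.62 log2 and the carboxylesterase Ces1g by 3.17 ± 0.70. Flna fell from 208 ± 110.0 to 67.0 ± 34.4 CPM, -1.64 ± 0.30 log2. The largest adjusted p of these 4 genes was 0.00407 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 7 exposed libraries lay on the same side of the control mean for each of them.

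Of the 43 NRF2 and glutathione genes, 15 rose and 28 did not pass, and 26 rose when adjusted over the list alone. The epoxide hydrolase Ephx1 rose by 2.55 ± 0.54 log2, catalase, Cat, by 1.20 ± 0.17 and the pentose phosphate enzyme Taldo1 by 1.06 ± 0.18. The glutathione transferase Gm3776, which is not among the 43, rose by 2.40 ± 0.41. The probe of Gm3776, like those of Gsta1 and Gsta2, may also detect transcripts of near-identical family members, so these genes are uncertain as single genes. In the xenobiotic list 8 of 33 rose, and 13 rose and 2 fell when adjusted over the list alone. The xenobiotic receptor Nr1i3 (CAR) rose by 1.11 ± 0.17 and the flavin monooxygenase Fmo5 by 0.85 ± 0.16. Among enterocyte genes 4 of 12 rose (6 adjusted over the list alone), with Klf4 at 1.5 ± 0.25. In the fatty acid list 5 of 27 rose (8 adjusted over the list alone), with the fatty aldehyde dehydrogenase Aldh3a2 at 0.81 ± 0.14, and in the hypoxia list 4 of 31 rose (5 adjusted over the list alone), with Bnip3 at 1.55 ± 0.41 and the glycolytic enzyme Tpi1 at 0.73 ± 0.16. Camera called all 5 lists higher with the preset correlation, and none with an estimated correlation, where the adjusted p was 0.0788 for NRF2, 0.258 for xenobiotic, 0.258 for enterocyte, 0.354 for fatty acid and 0.0788 for hypoxia.

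Of 8 smooth muscle genes 2 fell (5 adjusted over the list alone), and of 25 stroma genes 2 fell (4 adjusted over the list alone), with collagen Col6a3 at -1.09 ± 0.26 log2. Camera called both lists lower, with adjusted p = 0.0788 and 0.188 with an estimated correlation. Cd74 fell by 1.25 ± 0.29 log2. The acinar list had a median of -2.18 log2 over 16 genes, with 0 called by edgeR, and camera called it lower, with adjusted p = 0.322 with an estimated correlation. The camera calls of these 8 lists held with each library left out in turn, while the fatty acid genes that rose numbered 3 without control replicate 5. Without that library the difference from control in mean log2 CPM of the enterocyte list went from 0.77 to 0.35. With the acinar share as a covariate 9 NRF2 genes, 4 xenobiotic genes and 2 smooth muscle genes were called, and without the libraries over 50% acinar 10, 2 and 1. Nucb2, a calcium-binding protein of the Golgi, fell by 2.35 ± 0.63 log2; it was at -0.68 with the covariate, -0.96 without those libraries and -1.54 without control replicate 5, and passed in none of these fits.

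In all, 131 of 2541 probes passed, 96 higher and 35 lower. The split was 85 higher and 54 lower with DESeq2 size factors in edgeR, and 32 and 0 with library totals alone, which moved the median of all probes by 0.32 log2. The count was 213 with DESeq2, 70 with limma-voom, 29 with only the compared groups in the fit and 63 without the libraries over 50% acinar; with the acinar covariate it was 75, and 65 of the 131 were kept. Of the 17 passing genes named here, 11 kept their call with library totals alone, 11 with limma-voom and 10 with only the compared groups in the fit, and Ces1g, Col6a3 and Nucb2 lost theirs without the libraries over 50% acinar.

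Captan at 12000 ppm was set against control to find the response to the higher captan dose (n = 7 against 5). Many NRF2 genes and some genes of drug metabolism and lipid synthesis were higher, and Cd74 and a few genes of connective tissue were lower. Gsta2 rose from 240.1 ± 105 to 3061 ± 1975 CPM (mean ± SD), 3.67 ± 0.52 log2, and the cytochrome P450 Cyp2c29 from 35.6 ± 59.0 to 1236 ± 1156 CPM, 5.06 ± 1.06 log2. The quinone reductase Nqo1 rose by 2.23 ± 0.44 log2. Cd74 fell from 15984 ± 6617 to 4769.9 ± 1612 CPM, -1.74 ± 0.29 log2. The 4 genes had adjusted p of at most 0.00199 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 7 exposed libraries lay on the same side of the control mean for each of them. Nqo1 in captan 12000 ppm replicate 2, at 7.21 log2 CPM, nevertheless lay below control replicates 1 and 4, at 7.44 and 7.82, and in replicate 1, at 7.80, below control replicate 4.

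Of the 43 NRF2 and glutathione genes, 23 rose, and 29 rose when adjusted over the list alone. Cbr3 rose by 4.40 ± 0.66 log2, Gsta1 by 2.58 ± 0.39, Cat by 1.08 ± 0.17 and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, by 2.19 ± 0.58. The mean log2 CPM of the list was 7.11 and 7.10 in replicates 1 and 2, against at most 6.89 in a control library, and from 7.57 to 8.67 in the other 5. In the xenobiotic list 11 of 33 rose, and 14 rose and 2 fell when adjusted over the list alone. Besides Cyp2c29 they included Ces1g at 3.52 ± 0.71, the drug efflux pump Abcb1a at 1.40 ± 0.24, Nr1i3 at 1.33 ± 0.17 and Por at 1.22 ± 0.19. Of 22 lipid and sterol synthesis genes 3 rose, and 8 rose and 1 fell when adjusted over the list alone, with the malic enzyme Me1 at 1.63 ± 0.26. In the hypoxia list 7 of 31 rose, and 9 rose and 2 fell when adjusted over the list alone, with Pfkl at 1.5 ± 0.34. Among enterocyte genes 4 of 12 rose, and 7 rose and 2 fell when adjusted over the list alone, with Klf4 at 1.53 ± 0.25. Camera called these 5 lists higher with the preset correlation and none with an estimated correlation, where the adjusted p was 0.0601 for NRF2 and for hypoxia, 0.194 for xenobiotic and for lipid synthesis, and 0.319 for enterocyte. With control replicate 5 left out, camera did not call the enterocyte list (adjusted p = 0.102), and 1 lipid synthesis gene passed.

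Of 25 stroma genes 3 fell (4 adjusted over the list alone), with Col6a3 at -1.29 ± 0.26 log2 and the microfibril protein Fbn1 at -1.21 ± 0.29. Of 8 smooth muscle genes 2 fell (2 adjusted over the list alone), and of 18 myeloid and mast cell genes 2 fell (6 adjusted over the list alone). Camera called the 3 lists lower, with adjusted p = 0.194 with an estimated correlation for each. The acinar list had a median of -2.32 log2 (-4.83 without captan 12000 ppm replicate 7), with 0 of 16 called by edgeR. With the acinar share as a covariate 15 NRF2 and 7 xenobiotic genes were called, and without the libraries over 50% acinar 12 and 7. In all, 157 of 2541 probes passed, 118 higher and 39 lower, and with library totals alone, which moved the median by 0.44 log2, 75 and 4. The count was 261 with DESeq2, 94 with limma-voom, 29 with only the compared groups in the fit and 86 without the libraries over 50% acinar; without captan 12000 ppm replicate 3 it was 104. With the acinar covariate it was 86, 74 of the 157 were kept, and Gclc lost its call there and without the libraries over 50% acinar, where Fbn1 did too. Of the 17 passing genes named here, 15 kept their call with library totals alone, 13 with limma-voom and 12 with only the compared groups in the fit.

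Folpet at 6000 ppm was set against control to find the response to the lower folpet dose (n = 7 against 5). Some glutathione, drug metabolism and immediate early genes were higher, and some smooth muscle genes were lower. Gsta2 rose from 240.1 ± 105 to 2929 ± 902 CPM (mean ± SD), 3.61 ± 0.52 log2, and Ces1g from 62.0 ± 63.6 to 908 ± 244 CPM, 3.84 ± 0.72 log2. Fos, a subunit of the AP-1 transcription factor, rose by 1.21 ± 0.23 log2. Flna fell from 208 ± 110.0 to 57.9 ± 13.2 CPM, -1.84 ± 0.30 log2, and smooth muscle actin, Acta2, by 0.92 ± 0.21. The 5 genes had adjusted p of at most 0.00319 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 7 exposed libraries lay on the same side of the control mean for each of them.

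Of the 43 NRF2 and glutathione genes, 16 rose, and 23 rose when adjusted over the list alone. Cbr3 rose by 2.99 ± 0.61 log2, Taldo1 by 1.32 ± 0.18 and Cat by 1.26 ± 0.17. In the xenobiotic list 8 of 33 rose (10 adjusted over the list alone), with Por at 1.41 ± 0.19, Nr1i3 at 1.36 ± 0.17 and Fmo5 at 1.20 ± 0.16. In the hypoxia list 4 of 31 rose (5 adjusted over the list alone), with Bnip3 at 2.16 ± 0.42 and Car9 at 1.07 ± 0.24. Of 17 immediate early genes 4 rose (6 adjusted over the list alone), and of 12 enterocyte genes 4 rose (6 adjusted over the list alone); Klf4, which both lists hold, was at 1.35 ± 0.24. Camera called these 5 lists higher with the preset correlation and none with an estimated correlation, where the adjusted p was 0.0733 for NRF2, 0.0548 for hypoxia, 0.207 for xenobiotic, 0.207 for immediate early and 0.277 for enterocyte. Without control replicate 5 the differences from control in mean log2 CPM went from 0.84 to 0.49 for immediate early and from 0.74 to 0.32 for enterocyte. In the p53 list 2 of 26 rose and 1 fell (2 and 1 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 0.75 ± 0.18, and camera did not call the list (adjusted p = 0.606).

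Of 8 smooth muscle genes 4 fell (6 adjusted over the list alone), and of 25 stroma genes 2 fell (3 adjusted over the list alone), with Col6a3 at -1.12 ± 0.26 log2. Camera called both lists lower, with adjusted p = 0.0733 and 0.277 with an estimated correlation. It did not call the stroma list without control replicate 3 or 4 (adjusted p = 0.0588 and 0.0943); 4 stroma and 7 hypoxia genes passed without control replicate 5. Of 23 endoplasmic reticulum stress genes 3 fell (3 adjusted over the list alone), with the chaperone Hyou1 at -0.68 ± 0.16, and camera did not call the list (adjusted p = 0.209). Cd74 fell by 1.26 ± 0.29 log2. The acinar list had a median of -1.86 log2, with 0 of 16 called by edgeR. With the acinar share as a covariate 12 NRF2 and 3 smooth muscle genes were called, and without the libraries over 50% acinar 13 and 1. In all, 158 of 2541 probes passed, 117 higher and 41 lower, and with library totals alone, which moved the median by 0.28 log2, 50 and 1. The count was 225 with DESeq2, 97 with limma-voom, 77 with only the compared groups in the fit and 105 without the libraries over 50% acinar. With the acinar covariate it was 101, 83 of the 158 were kept and Hyou1 was not, and Acta2 and Car9 lost their calls without the libraries over 50% acinar. Of the 18 passing genes named here, 11 kept their call with library totals alone, 15 with limma-voom and 17 with only the compared groups in the fit.

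Folpet at 16000 ppm was set against control to find the response to the higher folpet dose (n = 7 against 5). Most of the measured NRF2 genes were higher, and some genes of smooth muscle, connective tissue and MHC class II were lower. The cytochrome P450 Cyp2a5 was at 0 in every control library and was at least 153-fold higher, taking 3 counts over the control group as the floor and provided that no low counts were set to 0 before deposit, which the sources used here do not say, at 25.3 ± 13.0 CPM (mean ± SD) after folpet; its probe may also detect near-identical family members. Nqo1 rose from 140.3 ± 57.1 to 828 ± 161 CPM, 2.56 ± 0.44 log2, and Gsta2 from 240.1 ± 105 to 4635 ± 930.2 CPM, 4.27 ± 0.53 log2. The MHC class II chain H2-Aa fell from 547 ± 315 to 68.1 ± 27.1 CPM, -3.01 ± 0.43 log2. The largest adjusted p of these 4 genes was 0.00134 (edgeR quasi-likelihood test, Benjamini-Hochberg). All 7 exposed libraries lay on the same side of the control mean for each of them.

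Of the 43 NRF2 and glutathione genes, 29 rose and 14 did not pass, and 31 rose when adjusted over the list alone. The cystine transporter Slc7a11 rose by 5.0 ± 1.26 log2, Cbr3 by 4.75 ± 0.67, UDP-glucose dehydrogenase, Ugdh, by 2.40 ± 0.31, Taldo1 by 1.58 ± 0.18 and Cat by 1.42 ± 0.17. The list's median was 1.42 log2, and camera called it higher both with the preset correlation and with adjusted p = 0.0210 with an estimated correlation. In the hypoxia list 8 of 31 rose and 1 fell (9 and 2 adjusted over the list alone), with Bnip3 at 2.47 ± 0.42, and the glycolytic enzymes Aldoa at 1.57 ± 0.21 and Tpi1 at 0.99 ± 0.16; camera called it with adjusted p = 0.0413 with an estimated correlation. Without control replicate 3 that p was 0.0575 for NRF2 and for hypoxia, and for hypoxia it also lay over 0.05 without control replicate 1 or 2 or folpet 16000 ppm replicate 2 or 6. In the xenobiotic list 9 of 33 rose and 1 fell (14 and 2 adjusted over the list alone), with Ces1g at 4.41 ± 0.75, Nr1i3 at 1.52 ± 0.18 and Por at 1.39 ± 0.19. Of 22 lipid and sterol synthesis genes 2 rose and 1 fell (3 and 1 adjusted over the list alone), with Acat2 at 1.15 ± 0.24 and Me1 at 1.73 ± 0.26. Camera called the xenobiotic and lipid synthesis lists higher, with adjusted p = 0.257 for each with an estimated correlation, but not the lipid synthesis list without control replicate 4 or 5 or folpet 16000 ppm replicate 3 (adjusted p = 0.0533, 0.0610 and 0.0541). Of 25 mitochondrial genes 6 rose (11 rose and 1 fell adjusted over the list alone), with the ATP synthase subunit Atp5a1 at 0.69 ± 0.16, and camera did not call the list (adjusted p = 0.0784). Its mean log2 CPM lay 0.41 above control, and 0.11 without control replicate 5, where 1 of its genes passed. The ERK phosphatase Dusp6 rose by 1.30 ± 0.29, and Mki67 did not pass at -0.51 ± 0.56.

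Of 8 smooth muscle genes 5 fell (5 adjusted over the list alone), with Flna at -2.24 ± 0.31 log2 and Acta2 at -0.98 ± 0.21. Of 25 stroma genes 5 fell (11 adjusted over the list alone), with Col6a3 at -1.70 ± 0.26 and the proteoglycan Bgn at -0.82 ± 0.16. Of 18 myeloid and mast cell genes 5 fell (1 rose and 6 fell adjusted over the list alone), with the complement subunits C1qb at -1.11 ± 0.19 and C1qc at -1.15 ± 0.20. Of 31 interferon and antigen presentation genes 5 fell (5 adjusted over the list alone), with Cd74 at -2.28 ± 0.29 besides H2-Aa. Camera called these 4 lists lower with the preset correlation and none with an estimated correlation, where the adjusted p was 0.0656, 0.0723, 0.205 and 0.485 in that order, and the interferon list was not called without control replicate 2 or 3 (adjusted p = 0.154 and 0.0527). The interleukin-1 receptor Il1r1 fell by 1.36 ± 0.31 log2. With the acinar share as a covariate 27 NRF2, 4 smooth muscle and 5 stroma genes were called, and without the libraries over 50% acinar 25, 3 and 6. In all, 320 of 2541 probes passed, 201 higher and 119 lower. The split was 167 higher and 151 lower with DESeq2 size factors in edgeR and 42 and 15 with library totals alone, and the count was 205 with only the compared groups in the fit. Library totals alone ended the calls of Acat2, Acta2, Atp5a1, Bgn, C1qc, Dusp6, Il1r1 and Tpi1, and limma-voom those of Il1r1 and Slc7a11.

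**Figure D2:**
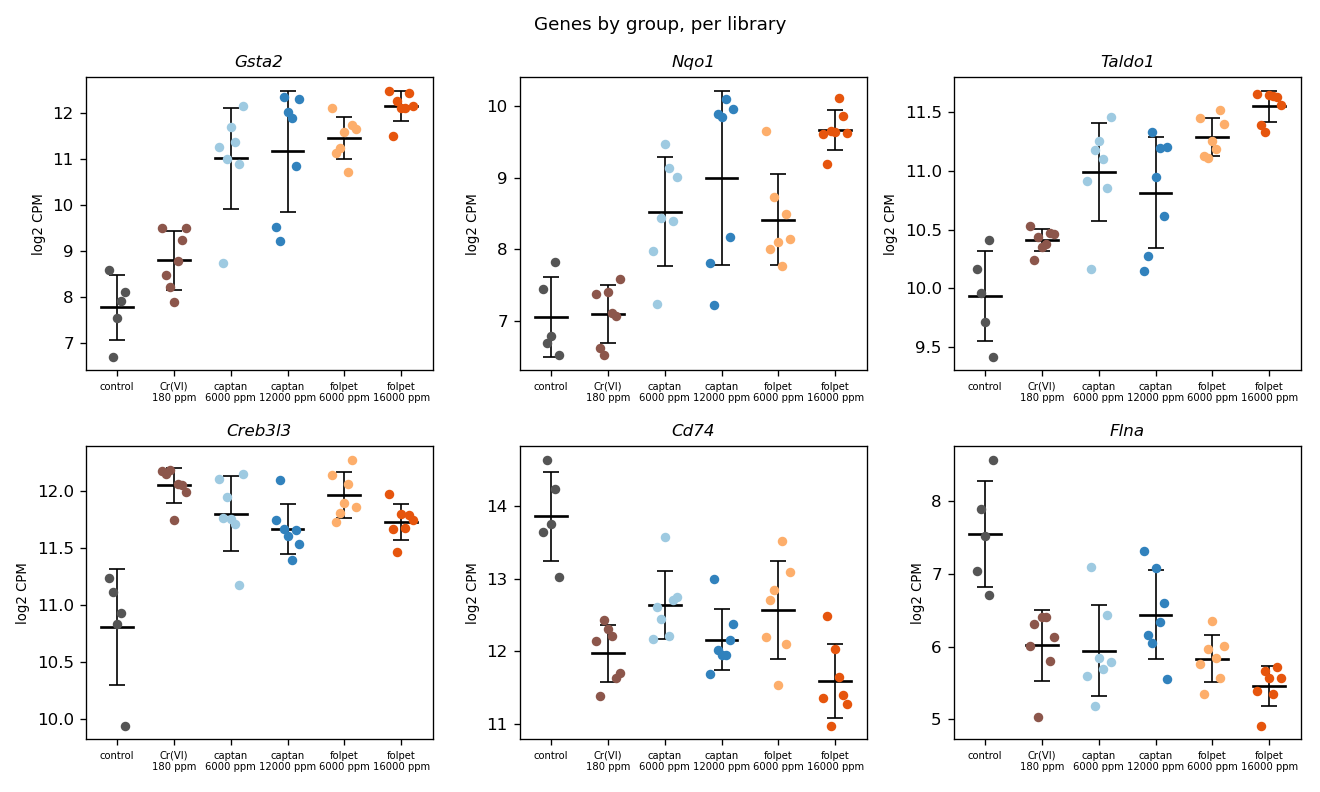
Log2 CPM (prior count 2) of 6 genes in each library (y axis) by group (x axis); points are libraries, horizontal lines group means and error bars ± SD. Gsta2, Nqo1 and Taldo1 belong to the NRF2 list, and Cd74 and Flna were lower than control in all 5 exposed groups.

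**Figure D3:**
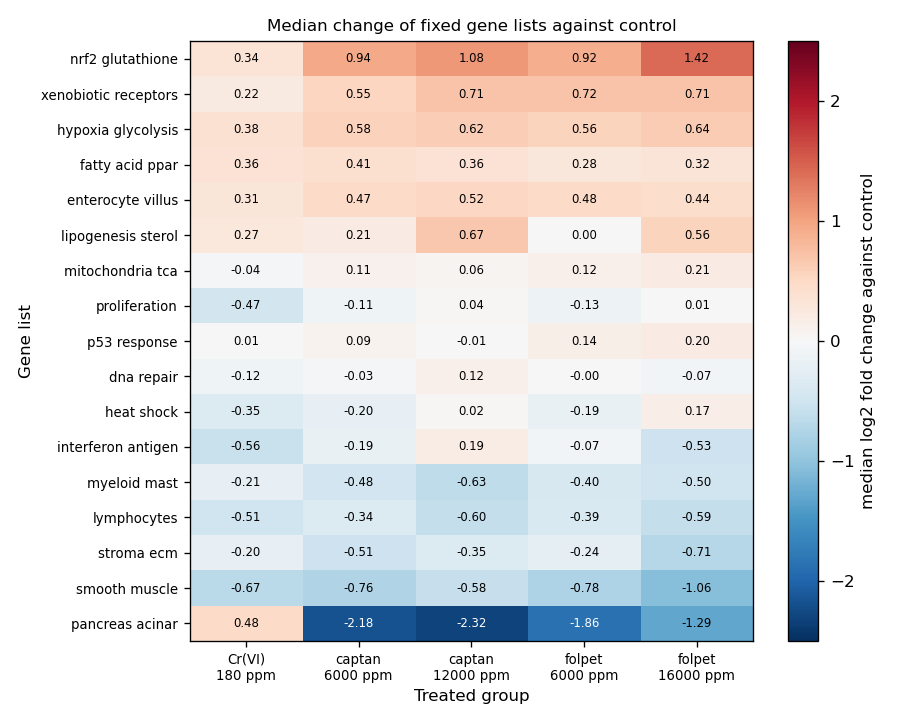
Median log2 fold change against control of 17 gene lists (down) in the 5 exposed groups (across), printed in each cell and shown as color from blue, lower, to red, higher. The NRF2 medians ran from 0.34 after Cr(VI) to 1.42 in folpet 16000 ppm.

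The 5 comparisons with control were then set side by side to see which genes changed in several exposures. 42 probes passed in the same direction in all 5, 35 higher and 7 lower. The higher ones included Klf4, Bnip3, Por, Car9, Nr1i3 and Cat, and the lower ones Cd74 and Flna. Cd74 ran from -1.25 ± 0.29 log2 with captan 6000 ppm to -2.28 ± 0.29 with folpet 16000 ppm, with -1.95 ± 0.29 after Cr(VI) (edgeR, n = 7 against 5 in each). In the 4 captan and folpet groups 74 probes passed in the same direction, 63 higher and 11 lower, and these added Gsta2, Cbr3, Ces1g, Taldo1 and Nqo1. Of the 74, 42 were kept with the acinar share as a covariate, 36 without the libraries over 50% acinar and 44 without control replicate 5. Of those that passed in all 5, 27, 14 and 21 were kept.

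At 6000 ppm captan and folpet shared 94 calls, 79 higher and 15 lower, where independent lists of the same sizes would share 4.42 and 0.565. Captan 12000 ppm and folpet 16000 ppm shared 134 (103 and 31, against 9.33 and 1.83). Cr(VI) shared 63 with captan 12000 ppm (48 and 15, against 3.48 and 1.17) and 93 with folpet 16000 ppm (60 and 33, against 5.93 and 3.56). The control libraries are common to each pair. In 40 simulations all libraries, controls included, were drawn from 1 mean per probe, and edgeR gave 0 shared calls. Calls are rare in data without changes, so this 0 does not bound what common controls add. With the controls split between the comparisons of a pair, the median of 20 fits was 18.5, 44.5, 14 and 25 shared calls in the same order, with fewer controls in each fit. The covariance of log2 fold changes across genes, which are not independent replicates, was 0.907, 0.962, 0.663 and 0.715, against 0.309, 0.304, 0.308 and 0.310 in the simulations. The correlations were 0.818, 0.724, 0.530 and 0.645, where the simulations gave between 0.582 and 0.591. The simulated probes varied independently, so shifts that many probes of 1 control library share are missing from these references.

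**Figure D4:**
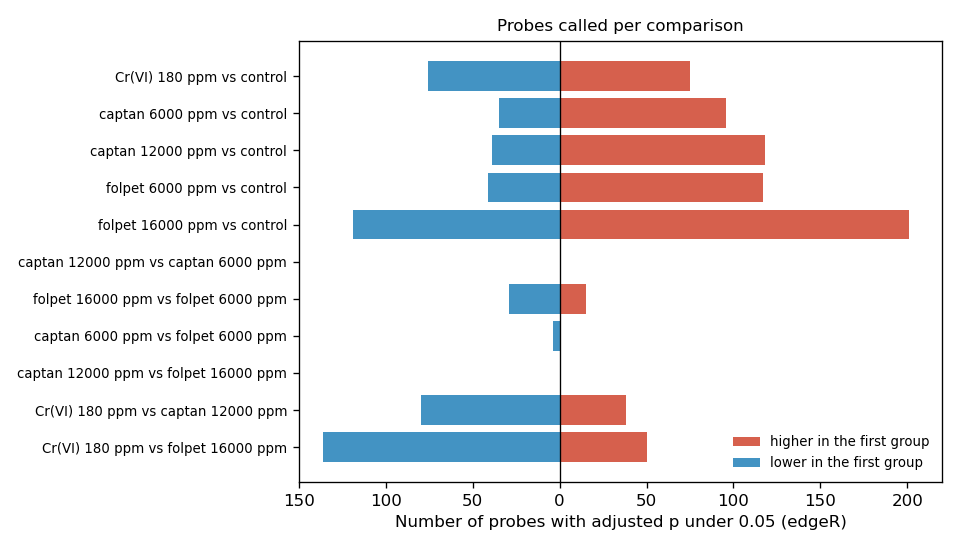
Number of probes that passed the edgeR test (x axis) in each of the 11 comparisons between groups (y axis), with bars to the right for probes higher in the first group and to the left for lower ones. Folpet 16000 ppm against control had 201 higher and 119 lower probes, and captan 12000 against 6000 ppm had 0.

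The higher dose of each fungicide was set against the lower one to find what the dose step added (n = 7 each). With folpet, the heat shock and sterol synthesis lists were higher at 16000 than at 6000 ppm. The inducible heat shock protein gene Hspa1b rose from 50.9 ± 32.3 to 934 ± 310.1 CPM (mean ± SD), 4.20 ± 0.75 log2, the NRF2 target Osgin1 by 1.46 ± 0.24, the squalene epoxidase Sqle by 1.32 ± 0.29 and the chaperonin subunit Tcp1 by 0.81 ± 0.16. The glucocorticoid-induced co-chaperone Fkbp5 fell from 4782 ± 775 to 1334 ± 390.0 CPM, -1.84 ± 0.35 log2, 4833414E09Rik by 1.6 ± 0.33 and H2-Aa by 1.68 ± 0.39. These 7 genes had adjusted p of at most 0.0151 (edgeR quasi-likelihood test, Benjamini-Hochberg). The probe of Hspa1b may also detect its near-identical neighbour Hspa1a.

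Of the 22 lipid and sterol synthesis genes 1 rose in the folpet step (3 adjusted over the list alone; median 0.51 log2), and of 20 heat shock genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.31). Camera called both lists higher, with adjusted p = 0.0422 for each with an estimated correlation, which lay over 0.05 in 9 and 10 of 14 fits without 1 library. In the NRF2 list 3 of 43 rose (5 adjusted over the list alone; median 0.51), with adjusted p = 0.269 with an estimated correlation by camera. In the interferon list 3 of 31 fell and in the stroma list 2 of 25 (3 and 2 adjusted over the list alone), with adjusted p = 0.543 and 0.434 with an estimated correlation by camera. In all, 44 probes passed, 15 higher and 29 lower; with library totals alone, which moved the median by -0.28 log2, it was 1 and 8, and H2-Aa, Osgin1, Sqle and Tcp1 did not pass. The count was 86 with DESeq2, 139 with limma-voom, 113 with only the compared groups and 71 without the libraries over 50% acinar. It was 25, 29 and 29 without folpet 6000 ppm replicates 2, 3 and 5, the last of which ended the call of H2-Aa (-1.38 log2), and 27, 27 and 28 without folpet 16000 ppm replicates 1, 3 and 5.

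With captan, the step from 6000 to 12000 ppm gave 0 probes by edgeR, 148 at an unadjusted p under 0.05, 0 with DESeq2 and 8 with limma-voom. It was 1 without captan 6000 ppm replicate 4, and also without captan 12000 ppm replicate 2 or 6. Nqo1 was at 0.69 ± 0.37 log2 and Gclc at 1.08 ± 0.49. Camera called the lipid and sterol synthesis list (median 0.32 log2) and the heat shock list (median 0.25) higher, with adjusted p = 0.0238 and 0.0424 with an estimated correlation; edgeR called 0 and 0 of their genes, and adjusted over the list alone 0 lipid genes and 1 higher and 1 lower heat shock genes. In 2 and 9 of 14 fits without 1 library that p lay over 0.05. The NRF2 list had a median of 0.21 log2, with adjusted p = 0.835 with an estimated correlation by camera. In simulated data for this comparison edgeR recovered 37.8% of 2-fold and 61.0% of 4-fold changes, so most 2-fold changes would not have been detected. The interaction test of the step between the compounds gave 0 probes by edgeR, with 168 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with limma-voom; the steps differ in size, 6000 to 12000 and 6000 to 16000 ppm.

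Captan and folpet at the matched dose of 6000 ppm were compared to find where the ring system goes with a different response (n = 7 each). The differences that passed were in 4 genes, and all were lower with captan. Ddit4, an inhibitor of mTOR signalling, was at 26.9 ± 14.5 CPM (mean ± SD) with captan and 126 ± 46.6 with folpet, -2.22 ± 0.43 log2. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was at -1.11 ± 0.17 log2, the antiproliferative gene Btg2 at -0.99 ± 0.20 and the NF-kB inhibitor Nfkbia at -0.64 ± 0.14. All 4 had adjusted p of at most 0.0122 (edgeR quasi-likelihood test, Benjamini-Hochberg). The count was 13 with DESeq2, 15 with limma-voom, 10 with only the compared groups, 1 with library totals alone and 10 without the libraries over 50% acinar. In data simulated from edgeR's own estimates for this comparison, DESeq2 gave 20% false calls in 1 simulation and edgeR 4.75% in 5. DESeq2 gave 1823 probes, Ddit4 among them, no adjusted p. With edgeR, Nfkbia did not pass without captan 6000 ppm replicate 1 (-0.60 log2) or 2 (-0.58) or without folpet 6000 ppm replicate 3 (-0.55).

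Camera called 0 lists at 6000 ppm, and none of 60 exact permutation tests of list scores, over both dose pairs, passed the Benjamini-Hochberg adjustment. The NRF2 score, the mean log2 CPM of its genes, was 7.72 ± 0.350 with captan and 7.82 ± 0.371 with folpet (SD), a difference of -0.10 (bootstrap 95% interval -0.47 to 0.24). Its median fold change between the compounds was 0.0095 log2 and its mean -0.023. Nqo1 differed by 0.13 ± 0.37 log2. The bootstrap 95% interval lay below 0, lower with captan, for the hypoxia and p53 scores. The hypoxia score differed by -0.17 (-0.31 to -0.039, exact permutation p = 0.0321, 0.385 after Benjamini-Hochberg adjustment). The p53 score differed by -0.27 (-0.52 to -0.026, exact permutation p = 0.0740, 0.584 adjusted). Both lists hold Ddit4, and the p53 list also holds Btg2. The median half-width of a 95% interval over the 2541 probes was 0.92 log2, and 1048 intervals lay within 1 log2 of 0, so for the other probes a 2-fold difference was not excluded.

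The highest doses differ, 12000 ppm for captan and 16000 ppm for folpet. Between them edgeR called 0 probes, with 193 at an unadjusted p under 0.05, 27 with DESeq2, 9 with limma-voom and 3 without the libraries over 50% acinar. Without captan 12000 ppm replicate 5 it was 3. Nqo1 was at -0.33 ± 0.37 log2 in captan against folpet. The NRF2 score differed by -0.39 (95% interval -0.92 to 0.12). The mitochondrial score had the smallest exact permutation p of the 60 tests. It differed by -0.21 (95% interval -0.29 to -0.13, exact p = 0.00117) and did not pass after Benjamini-Hochberg adjustment (0.0699). Camera with the preset correlation called 6 lists, among them NRF2 lower with captan (median -0.32 log2), and interferon (median 0.89), smooth muscle (median 0.53) and stroma (median 0.33) higher; edgeR called 0 of their genes, adjusted over the list alone 2 NRF2, 5 interferon, 2 smooth muscle and 0 stroma genes passed, and the adjusted p was 0.325 with an estimated correlation for each. Captan 12000 ppm replicate 2 had a mean log2 CPM of 6.58 in the interferon list, against at most 4.72 in the other captan libraries; without it the median was 0.21, the list was not called (adjusted p = 0.105) and the NRF2 median was -0.14. Without captan 12000 ppm replicate 1 the NRF2 and smooth muscle medians were -0.17 and 0.22, and smooth muscle and stroma were not called (adjusted p = 0.0557 and 0.110), nor was stroma without folpet 16000 ppm replicate 3 (adjusted p = 0.0803); without captan 12000 ppm replicate 6 the NRF2 median was -0.20. The acinar share was 9.70 ± 18.4% with captan and 23.9 ± 10.2% with folpet.

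Cr(VI) was set against each high fungicide dose to find which genes separate the metal from the fungicides (n = 7 each). Many NRF2 genes and some drug metabolism genes were lower after Cr(VI) than with either fungicide. Cyp2a5 was at 0 in every Cr(VI) library, at least 208-fold lower than with captan 12000 ppm and at least 217-fold lower than with folpet 16000 ppm, taking 3 counts over the Cr(VI) group as the floor, again provided that no low counts were set to 0 before deposit. Nqo1 was at 141 ± 37.4 CPM (mean ± SD) after Cr(VI) against 659.9 ± 417 with captan and 828 ± 161 with folpet, -2.23 ± 0.38 and -2.56 ± 0.39 log2. Gclc was at -2.31 ± 0.52 log2 against captan and -2.31 ± 0.52 against folpet, and the P450 Cyp2c29 at -7.21 ± 1.02 against captan. The trypsin genes Gm5771 and Prss1, which are made by pancreatic acinar cells and whose probes may detect each other's transcripts, were higher after Cr(VI) than with captan by 7.85 ± 1.54 and 6.48 ± 1.66 log2, and Gm5771 than with folpet by 5.82 ± 1.40. The angiogenic factor Vegfa was higher than with folpet by 0.96 ± 0.24. The largest adjusted p of these genes was 0.0146 (edgeR quasi-likelihood test, Benjamini-Hochberg).

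Of 43 NRF2 genes 15 were lower than with captan (27 adjusted over the list alone; median -0.62 log2) and 27 lower than with folpet (29 adjusted over the list alone; median -1.08). Of 20 heat shock genes 4 were lower and 1 higher than with captan (9 and 1 adjusted over the list alone) and 6 lower than with folpet (10 adjusted over the list alone). In the xenobiotic list 6 and 9 of 33 were lower (11 against captan, and 11 with 1 higher against folpet, adjusted over the list alone), with adjusted p = 0.394 and 0.513 with an estimated correlation by camera. For the NRF2 and heat shock lists, which camera called lower in both comparisons, it was 0.173 for each against captan, 0.0171 for NRF2 and 0.0288 for heat shock against folpet with an estimated correlation; the last was 0.0736 without Cr(VI) replicate 2 and 0.0509 without Cr(VI) replicate 4. Of 25 stroma genes 4 and of 18 myeloid genes 4 were higher than with folpet (7 and 6 adjusted over the list alone), with adjusted p = 0.0880 and 0.231 with an estimated correlation by camera. The acinar share was 49.7 ± 24.3% after Cr(VI) against 9.70 ± 18.4% with captan and 23.9 ± 10.2% with folpet, and the acinar list had medians of 2.69 and 1.64 log2, with 1 of 16 genes called in each comparison; without captan 12000 ppm replicate 7 the median against captan was 5.41, with 4 called.

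In all, 118 probes differed between Cr(VI) and captan 12000 ppm, 38 higher and 80 lower, and 186 between Cr(VI) and folpet 16000 ppm, 50 and 136. With library totals alone, which moved the medians by -0.72 and -0.28 log2, the splits were 8 and 496 against captan and 4 and 62 against folpet, and with DESeq2 size factors in edgeR 77 and 103 against folpet. With the acinar covariate 45 probes passed against captan, 32 of them among the 118, without Gclc and Prss1 (3.92 log2), and Gm5771 moved to 4.82 against captan and to 2.31, without a call, against folpet. Without the libraries over 50% acinar 43 passed against captan and Gclc did not, limma-voom ended the calls of Cyp2c29, Gm5771 and Prss1 there, and without captan 12000 ppm replicate 7 Prss1 was at 9.78 log2. Against folpet limma-voom called 297 probes, and library totals alone ended the call of Vegfa.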

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

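The tests of glutathione transferase probes, of cells outside the epithelium and of the probes common to the captan and folpet groups were chosen only after the results they bear on had been seen, as were the alternatives on the acinar share and the fits of lists without 1 library. The first pattern is the rise of 29 of 43 NRF2 genes with folpet 16000 ppm. A lower acinar share as the whole cause is argued against by the 27 of the 29 that still passed with the share as a covariate, and control replicate 5 as the whole cause by the 28 that passed without it; without the libraries over 50% acinar 25 NRF2 genes passed. Probes shared between glutathione transferase family members could raise those genes together, but 23 of the 36 NRF2 genes outside that family passed too. A response to folpet, which the design names, stays open as a hypothesis found on the same data, and other differences between the sections were not tested.

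The second pattern is the fall of 10 smooth muscle and stroma genes with folpet 16000 ppm. With the acinar share as a covariate 8 of them passed, and without control replicate 5 8, which argues against either as the whole cause; without the libraries over 50% acinar 3 smooth muscle and 6 stroma genes passed. A lower share of all cells outside the epithelium in the sections may account for the fall and cannot be told apart from a change in these cells. The scores of 6 lists of such cells differed from control by -1.08 log2 for smooth muscle to -0.0037 for endothelium, a gap of 1.07 whose bootstrap 95% interval ran from 0.000794 to 2.24; with each library left out in turn the gap ran from 0.75 without control replicate 5 to 1.36 without control replicate 1, and endothelium, at -0.43 without control replicate 5, from -0.49 without control replicate 2 to 0.37 without control replicate 3. The intervals of all lists but smooth muscle held 0 (4 of the 6 lay below 0 without control replicate 5), and the bound for this test was tightened after the gap was seen, so it decides nothing. Adipose, another list of cells outside the epithelium with 5 tested genes, was not among the 6. Its score went the other way, 1.28 log2 above control and 0.82 without control replicate 5, and no interval was computed for it.

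The third pattern is the 74 probes that passed in the same direction in all 4 captan and folpet groups. These groups share the control libraries and have a lower acinar share than control. With the share as a covariate 42 of the 74 passed in all 4, but without the libraries over 50% acinar only 36. The latter fit also lacks control replicates 4 and 5, so calls may be lost there for fewer controls alone. An effect of the acinar share on the pattern thus cannot be told apart from one of the exposures. Without control replicate 5 44 passed, which argues against that library as the cause for those probes and leaves it open for the others. A response common to both fungicides, which the design names, stays open too.

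For each comparison 100 splits of the same libraries into groups of the same sizes were tested, the real one included. A share of 1 split in 100 is the lowest these splits can give, and it was not adjusted over the comparisons. Such a share argues against a chance split of the libraries without excluding it. It does not bear on differences that go with the real groups, such as the acinar share. In several comparisons 1 split, the real one, gave as many probes. This held against control for Cr(VI) at 151 (highest other 16), captan 6000 ppm at 131 (highest other 19), captan 12000 ppm at 157 (highest other 112), folpet 6000 ppm at 158 (highest other 39) and folpet 16000 ppm at 320 (highest other 90). It also held for the folpet dose step at 44 (highest other 0), captan against folpet at 6000 ppm at 4 (highest other 1), and Cr(VI) against captan 12000 ppm at 118 (highest other 77) and against folpet 16000 ppm at 186 (highest other 48). For the captan dose step at 0 (highest other 25), captan against folpet at the higher doses at 0 (highest other 0) and the interaction at 0 (highest other 31), the real split gave 0, so all 100 splits gave as many by construction and the count says nothing about chance. For the captan dose step and the interaction, the splits that gave 25 and 31 probes may reflect a structure of the libraries other than their groups, which was not tested.

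In 394 groups of values (totals, probes above 0, acinar share, mean log2 CPM of 30 lists and named genes), each from the libraries of 1 group, 47 values of 19 libraries stood farther from the rest of their group than Dixon's critical value allows. For independent groups of normal values chance alone gives about 1 in 20, 19.7 here. These groups share libraries and genes and some values are counts of 0, so 47 against 19.7 is no test of chance. Captan 12000 ppm replicate 7 had the highest total count of its group, 6109418, and the highest acinar share there, 50.3%. Folpet 6000 ppm replicate 5 had the fewest probes above 0 of its group, 2013. Among the means of lists, 10 of the 21 values apart were of control replicate 5, which was lowest in enteroendocrine and tuft at 2.5, enterocyte at 8.18, fatty acid at 6.57, lipid synthesis at 3.04, NRF2 at 5.40, immediate early at 3.02, ER stress at 5.19, interferon at 1.53, apoptosis at 3.96 and mitochondrial at 7.30. The lowest of their groups were also folpet 6000 ppm replicate 5 in proliferation at 3.61 and lipid synthesis at 4.33, captan 6000 ppm replicate 3 in fatty acid at 7.56 and endothelium at 1.83, folpet 16000 ppm replicate 2 in NRF2 at 7.96 and bile acid at 2.63, folpet 16000 ppm replicate 1 in neural at 1.06, Cr(VI) replicate 5 in acinar at 8.43 and folpet 6000 ppm replicate 1 in acinar at -0.44. The highest of their groups were also captan 12000 ppm replicate 2 in interferon at 6.58 and apoptosis at 5.58. Among genes, a log2 CPM of -1.26 stands for a count of 0, which in a single library says little about a low transcript. Control replicate 5 stood apart in log2 CPM with Rab31 at -1.26, Bnip3 at -1.26, Hsd3b2 at -1.26, Mcm7 at 8.59, Mki67 at -1.26, Fmo5 at 7.79, Dusp6 at 5.72 and C1qb at 7.03. So did, in log2 CPM, control replicate 2 with Capg at -1.26, Cr(VI) replicate 6 with Capg at 8.51 and Ccna2 at 6.24, Cr(VI) replicate 4 with Creb3l3 at 11.74 and captan 6000 ppm replicate 4 with Cd74 at 13.57. Other such libraries were Cr(VI) replicate 2 with Cdkn1a at 8.64, captan 6000 ppm replicate 2 with Gsta2 at 8.74, Ephx1 at 7.79 and Gm3776 at 12.32, folpet 16000 ppm replicate 2 with Gsta2 at 11.50 and captan 6000 ppm replicate 6 with Nr1i3 at 8.79, and captan 12000 ppm replicate 1 with Fbn1 at 6.76, folpet 16000 ppm replicate 3 with C1qc at 5.31, Cr(VI) replicate 5 with Prss1 at 6.73 and folpet 16000 ppm replicate 5 with Vegfa at 5.80. Control replicate 5 held 18 of the 47.

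The dose steps of captan and folpet differed by camera with the preset correlation in 5 lists, with median interaction values of -0.42 log2 for the NRF2 list, 0.87 log2 for the interferon list, 0.55 log2 for the stroma list, -0.75 log2 for the acinar list and -0.19 log2 for the mitochondrial list. With an estimated correlation their adjusted p ran from 0.620 to 0.695, and edgeR called 0 probes. Without captan 12000 ppm replicate 2, the interferon and NRF2 values were 0.19 and -0.28 and neither list was called (adjusted p = 0.289 and 0.0680). The acinar value was -3.50 without captan 12000 ppm replicate 7 and -0.37 without folpet 16000 ppm replicate 1.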

How the results depend on the processing

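The alternatives on the acinar share, and those leaving out a library for lists and shared calls, were chosen only after the data were seen. Of the results of genes under the rule, 286 of 291 kept their direction and their side of the threshold with DESeq2 size factors, 290 of 291 with upper-quartile factors, 277 of 291 without a filter, 283 of 291 without robust dispersion, 283 of 291 with the probes of a gene summed, 274 of 280 with every library thinned to 1763440 counts, the smallest total, and 263 of 267 with DESeq2, where it gave an adjusted p. Fewer held with limma-voom (188 of 291), only the compared groups in the fit (150 of 262), the acinar covariate (222 of 291), libraries over 50% acinar left out (183 of 291) and library totals alone (125 of 291). Of 82 list calls by camera, 66 held with the covariate, 63 without those libraries, 76 without control replicate 5, 71 with library totals alone, 54 by fry and 8 with an estimated correlation. With each library of the compared groups left out in turn, 59 of the 82 held in every fit, and 1 of those 8. Library totals alone also moved the median of all probes by 0.11 log2 for the captan dose step, 0.44 for captan 12000 against folpet 16000 ppm and 0.40 for the interaction. No library fell under the limit set for low depth, so leaving out shallow libraries was not run. No paired analysis was possible because the labels give no replicate numbers that groups share. Where a result changed, the cause was not tested, except that a higher threshold admits more probes.

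The counts of called probes that moved by over a factor of 1.5, against control where no other group is named, are given by setting. With library totals alone the counts were 14 for Cr(VI), 32 for captan 6000 ppm, 79 for captan 12000 ppm, 51 for folpet 6000 ppm, 57 for folpet 16000 ppm, 9 for the folpet dose step, 1 for captan against folpet at 6000 ppm, 504 for Cr(VI) against captan 12000 ppm and 66 for Cr(VI) against folpet 16000 ppm. DESeq2 gave 240 for Cr(VI), 213 for captan 6000 ppm, 261 for captan 12000 ppm, 86 for the folpet dose step, 13 for captan against folpet at 6000 ppm, 27 for captan 12000 against folpet 16000 ppm and 185 for Cr(VI) against captan 12000 ppm. By limma-voom they were 71 for Cr(VI), 70 for captan 6000 ppm, 94 for captan 12000 ppm, 97 for folpet 6000 ppm, 8 for the captan dose step, 139 for the folpet dose step, 15 for captan against folpet at 6000 ppm, 9 for captan 12000 against folpet 16000 ppm, 188 for Cr(VI) against captan 12000 ppm, 297 for Cr(VI) against folpet 16000 ppm and 1 for the interaction. With only the compared groups in the fit they were 28 for Cr(VI), 29 for captan 6000 ppm, 29 for captan 12000 ppm, 77 for folpet 6000 ppm, 205 for folpet 16000 ppm, 113 for the folpet dose step and 10 for captan against folpet at 6000 ppm. A threshold of 0.1 gave 251 for Cr(VI), 223 for captan 6000 ppm, 251 for captan 12000 ppm, 69 for the folpet dose step, 10 for captan against folpet at 6000 ppm and 192 for Cr(VI) against captan 12000 ppm. With the acinar share as a covariate they were 75 for captan 6000 ppm, 86 for captan 12000 ppm, 101 for folpet 6000 ppm and 45 for Cr(VI) against captan 12000 ppm. Without the libraries over 50% acinar they were 51 for Cr(VI), 63 for captan 6000 ppm, 86 for captan 12000 ppm, 105 for folpet 6000 ppm, 71 for the folpet dose step, 10 for captan against folpet at 6000 ppm, 3 for captan 12000 against folpet 16000 ppm and 43 for Cr(VI) against captan 12000 ppm.

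Leaving out each library in turn gave from 115 to 159 probes for Cr(VI), 93 to 161 probes for captan 6000 ppm, 104 to 200 probes for captan 12000 ppm, 122 to 174 probes for folpet 6000 ppm, 262 to 318 probes for folpet 16000 ppm, 0 to 1 probes for the captan dose step, 25 to 47 probes for the folpet dose step, 3 to 6 probes for captan against folpet at 6000 ppm, 0 to 3 probes for captan 12000 against folpet 16000 ppm, 88 to 137 probes for Cr(VI) against captan 12000 ppm, 150 to 186 probes for Cr(VI) against folpet 16000 ppm and 0 throughout for the interaction.

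With the controls split, the calls shared numbered 18.5 for captan 6000 ppm and folpet 6000 ppm, 44.5 for captan 12000 ppm and folpet 16000 ppm, 14 for Cr(VI) and captan 12000 ppm and 25 for Cr(VI) and folpet 16000 ppm. At a threshold of 0.1, the calls shared numbered 146 for captan 6000 ppm and folpet 6000 ppm, 211 for captan 12000 ppm and folpet 16000 ppm, 103 for Cr(VI) and captan 12000 ppm, 113 for the 4 captan and folpet groups and 95 for Cr(VI), captan 12000 and folpet 16000 ppm together. With the acinar covariate, the calls shared numbered 57 for captan 6000 ppm and folpet 6000 ppm, 77 for captan 12000 ppm and folpet 16000 ppm, 41 for Cr(VI) and captan 12000 ppm, 46 for the 4 captan and folpet groups and 39 for Cr(VI), captan 12000 and folpet 16000 ppm together. Without the libraries over 50% acinar, the calls shared numbered 52 for captan 6000 ppm and folpet 6000 ppm, 75 for captan 12000 ppm and folpet 16000 ppm, 26 for Cr(VI) and captan 12000 ppm, 41 for Cr(VI) and folpet 16000 ppm, 18 for all 5 exposed groups, 42 for the 4 captan and folpet groups and 25 for Cr(VI), captan 12000 and folpet 16000 ppm together. Without control replicate 5, the calls shared numbered 73 for captan 6000 ppm and folpet 6000 ppm, 110 for captan 12000 ppm and folpet 16000 ppm, 49 for Cr(VI) and captan 12000 ppm, 72 for Cr(VI) and folpet 16000 ppm, 22 for all 5 exposed groups, 46 for the 4 captan and folpet groups and 43 for Cr(VI), captan 12000 and folpet 16000 ppm together. The original numbers were 94 for captan 6000 ppm and folpet 6000 ppm, 134 for captan 12000 ppm and folpet 16000 ppm, 63 for Cr(VI) and captan 12000 ppm, 93 for Cr(VI) and folpet 16000 ppm, 42 for all 5 exposed groups, 74 for the 4 captan and folpet groups and 60 for Cr(VI), captan 12000 and folpet 16000 ppm together; the fits of split controls have fewer control libraries.

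Some log2 values turned direction. They moved from 0.18 to -0.10 for Cdkn1a for Cr(VI) against control with library totals alone, from -1.66 to 0.050 for Aldh7a1 for captan 12000 ppm against control with the acinar covariate, from -0.53 to 0.055 for Bgn for captan 12000 ppm against control with library totals alone and from 0.13 to -0.060 for Nqo1 for captan 6000 ppm against folpet 6000 ppm without captan 6000 ppm replicate 4. They also moved from 1.65 to -0.27 for Aldh7a1 for Cr(VI) against captan 12000 ppm with the acinar covariate, from 1.79 to -0.091 for Rap1gap for Cr(VI) against captan 12000 ppm with the acinar covariate, from -1.86 to 0.73 for the acinar list median for folpet 6000 ppm against control with the acinar covariate and from 1.64 to -1.82 for the acinar list median for Cr(VI) against folpet 16000 ppm with the acinar covariate. For Nqo1 in captan against folpet at 6000 ppm, leaving out each library in turn gave from -0.060 to 0.43 log2. The cause was not tested.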

Other observations

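The glucocorticoid list tested here was chosen only after the genes that prompted it had been seen. Genes of DNA repair and of the p53 response were looked at in each comparison with control. Of 34 DNA repair genes, edgeR called 2, 0, 0, 0 and 0 lower in Cr(VI), captan 6000 ppm, captan 12000 ppm, folpet 6000 ppm and folpet 16000 ppm in that order (2, 0, 0, 0 and 0 adjusted over the list alone), and of 26 p53 genes 0, 0, 0, 2 and 1 higher and 0, 1, 1, 1 and 2 lower (0, 0, 0, 2 and 1 and 0, 1, 1, 1 and 2 adjusted over the list alone). Of all tested probes, 5.94%, 5.16%, 6.18%, 6.22% and 12.6% passed in the same order. Camera called neither list in any of the 5 comparisons, with a lowest adjusted p of 0.591 for DNA repair and 0.507 for p53. Of 32 listed crypt stem cell genes 7 were measured, and the markers Lgr5 and Olfm4 were not. The 7 had medians between -0.77 and -0.32 log2, with 0 called by edgeR and a lowest camera adjusted p of 0.119.

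Among 24 growth factor genes 3, 1, 4, 0 and 3 fell and 0, 0, 0, 1 and 0 rose in the same order (3, 1, 5, 0 and 3 and 2, 0, 1, 1 and 0 adjusted over the list alone), and among 22 lymphocyte genes 2, 0, 1, 0 and 2 fell (3, 0, 1, 0 and 2 adjusted over the list alone), with lowest camera adjusted p of 0.126 and 0.0624. In the 7 iron and heme genes 1, 1, 2, 1 and 2 rose (2, 1, 2, 1 and 2 adjusted over the list alone) with a lowest camera adjusted p of 0.123. In the 6 circadian genes 1, 1, 1, 1 and 1 rose; camera called that list higher after Cr(VI) (median 0.51 log2), with adjusted p = 0.144 with an estimated correlation, but not without control replicate 1 or 4 (adjusted p = 0.0889 and 0.0918), fits chosen after the data were seen.

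Tsc22d3, Ddit4 and Nfkbia, which were higher with folpet than with captan at 6000 ppm, and Fkbp5, which was higher with folpet at 6000 than at 16000 ppm, are textbook glucocorticoid-induced genes. A stronger glucocorticoid response with folpet 6000 ppm was put forward as a hypothesis, and tested on other genes of such a response, of which 9 of 24 were measured. Tsc22d3, Ddit4, Btg2, Nfkbia, Fkbp5, Glul and Sesn1 were left out of this list. The mean log2 CPM of the 9 genes was 4.47 ± 0.592 with folpet 6000 ppm and 4.42 ± 0.458 with captan 6000 ppm (SD, n = 7 each), a difference of 0.048 (bootstrap 95% interval -0.51 to 0.52, exact permutation p = 0.875). Against folpet 16000 ppm the difference was 0.43 (-0.069 to 0.84, exact p = 0.114, 0.341 after Benjamini-Hochberg adjustment over 3 tests) and against control 0.040 (-0.42 to 0.38). The interval is too wide to decide, and the hypothesis may hold or not.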
